A study of Mus musculus with 4 samples.

How the data were processed

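The data are Visium spatial transcriptomics from 4 capture frames, each holding cryosections of fresh-frozen mouse posterior eyes on a grid of barcoded spots. The deposited matrices hold counts, as whole numbers of unique molecular identifiers (UMIs), which the authors made from the sequencing reads. They were written by Space Ranger 2.0.0 per the file headers, with mm10 as the reference per the submitters' processing notes. Aligner settings and the gene annotation release are not given in the sources used here. All 4 frames were used, 1 library per frame, and only the spots called as lying over tissue entered the values. The frames held 1201, 1243, 1056 and 1103 such spots and 895894, 1066633, 885454 and 674029 UMIs. Median UMIs per spot were 531, 628, 630.5 and 430, and median genes per spot were 305, 358, 342 and 230. Of 32285 genes in the matrices, 17463 had at least 1 UMI. The 38 symbols shared by more than 1 gene were kept apart by gene identifier. No feature was named after a viral vector or a fluorescent protein, so vector transcripts were not measured separately from mouse transcripts. Images were not used here, and no spot was treated as a single cell.

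Regions were drawn from a fixed panel of 160 genes in 11 classes. Spots with at least 20 panel UMIs were scaled to 10000 counts, log-transformed, standardised with values limited to 10, and reduced to 10 principal components. A graph of 15 neighbours was partitioned with Leiden at resolution 0.6. A cluster took the class that held most of its 10 leading panel genes, provided that class held at least 3. Regions carry short names after those leading genes and are mixtures of cells. A share is a share of clustered spots.

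For comparisons, UMIs were summed per frame and region, so that n is the number of frames. A frame entered a comparison with at least 10 spots in both regions, and at least 3 frames were needed. The comparisons were inner retina (inner nuclear plus ganglion regions) minus photoreceptor region, outer coat (pigmented plus fibrous regions) minus neural retina (photoreceptor, inner nuclear and ganglion regions), and ganglion minus inner nuclear region. Panel genes were left out of library sizes and tests because they drew the regions. The same spots drew the regions and were tested. A version with regions drawn from a random 50% of the UMIs and tests on the other 50% addresses this only in part for the inner retina and ganglion comparisons. For the coat it does so poorly, since a cluster led by muscle and pigment epithelium genes stayed unnamed there and left the coat. The inner nuclear region was redrawn there too, with 158 spots in frame 4 against 68 in the main setting. It took in a cluster of 401 spots led by the photoreceptor panel gene Rp1. Frames served as the replicate block because both regions of a pair come from the same frame. The correlation of a pair's leftover values after region means were removed was 0.132, 0.044, 0.135 and 0.151 for the inner retina comparison, 0.095, 0.064, 0.083 and 0.132 for the coat and 0.083, 0.094, 0.124 and 0.105 for ganglion against inner nuclear, so pairing was weak in these values.

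Genes passed filterByExpr with a minimum count of 10, library sizes were scaled by TMM, and edgeR's robust quasi-likelihood test was applied with Benjamini-Hochberg adjustment and a limit of 0.05. Words for a change are used only for genes that passed this test. Adjusted p-values in the text come from this test, and those for lists come from camera or fry. Log2 folds are fitted across frames, and the ± value beside a fold is the SD of the frames' own log2 folds with a prior count of 2, which draws low counts toward 0. CPM are UMIs scaled to a common library total of all UMIs of the frame or region, panel genes among them. A fold against a region with 0 UMIs is given as at least a number, with a floor of 3 UMIs over the region. Counting error of the higher side is left out, so such a number is not a 95% limit. With 1 to 3 UMIs on the lower side the ratio is given with a 95% counting interval.

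There were 22 fixed gene lists, holding 566 genes of which 561 were in the matrices. Norrin, Ntf4 and Cralbp were not among the symbols, and Aldoa and Ddit3 were left out because their symbols were shared by more than 1 gene. Each list was tested against the other genes with camera at a preset correlation of 0.01 and again with an estimated correlation. The fry test asks whether the genes of a list differ at all, on balance 1 way or in either direction, and does not compare them with other genes. Named genes are the 10 largest positive and 10 largest negative folds among those that passed, up to 3 genes per list with the lowest p-value, and 10 genes fixed in advance: Wif1, Tcf4, Ctnnb1, Axin2, Lef1, Ccnd1, Dkk3, Sfrp1, Gfap and Apoe. The text gives most, not all, of the genes that this rule names. Any gene named outside it is said to be chosen after its value was seen.

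The panel, lists, comparisons, tests and most alternatives were fixed before the data were examined. Alternatives set in advance were DESeq2, plain library sizes, panel genes kept in the library sizes, no filter on low counts, no mitochondrially encoded genes, no replicate block, each frame left out, Leiden at resolutions 0.3 and 1, k-means, at least 50 or at least 10 panel UMIs, and regions from a random 50% of the UMIs. For frame values they were CPM without mitochondrially encoded genes and CPM without panel genes. Alternatives chosen after seeing the data were the comparisons without a ganglion cluster of low folds, coat spots with at most 5% photoreceptor panel UMIs, and a whole further comparison of myelin minus ganglion regions in 3 frames. Splits of the region sums of a comparison into other groups of the same size measured how many genes pass under other labels.

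The calculation was tried on simulated counts with regions and folds set in advance. Of 2491 simulated spots, 97.8% received the right region. These spots were drawn from the pooled profiles of regions found here, without mixing of regions in a spot. A high share was therefore built in, and it does not measure accuracy on the real spots. At a simulated 2-fold difference 62.7%, 44.8% and 46.3% of genes were recovered in the inner retina, coat and ganglion comparisons, at 4-fold 89.4%, 74.2% and 77.3%, and 8.4%, 1.1% and 3.3% of calls were false. In each comparison 67, 67 and 66 genes were changed at 1.5-, 2- and 4-fold, far fewer than passed in the data. Simulated frames shared 1 profile and differed only in depth, so these rates may not hold for the real comparisons. Software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.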

Results

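Posterior eyes of C57BL/6J mice were profiled by Visium spatial transcriptomics, which counts the RNA captured under each spot of a grid as unique molecular identifiers (UMIs). There were 4 capture frames with 4603 spots over tissue and 3522010 UMIs. The study design names Wif1, a secreted inhibitor of Wnt signalling, as the gene delivered with an AAV2/2 vector, and names a control and retinas at 2 and 4 weeks after injection. All 4 frames carry the same treatment label, naive plus AAV2/2, so the control and the 2 later conditions cannot be compared here. Every comparison is therefore between regions of the same frames, and its p-values measure spread between these frames, which may be technical. Spots over tissue formed 4, 6, 4 and 3 separate pieces in frames 1 to 4. The labels do not say whether a frame holds both naive and injected sections, so values of a frame or region may pool conditions.

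The retina was read through genes of its main layers, with n = 4 frames and levels in CPM (UMIs scaled to a common library total) given as mean ± SD. The rod arrestin gene Sag reached 1586 ± 173 CPM. Ganglion cell genes were also abundant, with the neurofilament gene Nefl at 4221 ± 725 CPM and the synuclein gene Sncg at 941 ± 121. Among genes of glia, Glul, which makes glutamine synthetase, stood at 844 ± 191 CPM, the lipid carrier gene Apoe at 632 ± 96.0, the filament gene Vim at 126 ± 21.0 and the complement gene C1qa at 43.7 ± 15.7. Gfap, a filament gene of reactive glia, ranged from 98.2 to 344 CPM with a mean of 229.7 ± 115. Outside the neural layers, the thyroid hormone carrier gene Ttr had 971 ± 343 CPM and the collagen gene Col1a1 384 ± 45.8. The nuclear RNA Malat1 had 866 ± 167 CPM and the mitochondrial gene mt-Co1 4012 ± 383.

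Clusters of 160 panel genes separated the tissue into 9 regions, named here after their leading genes. A photoreceptor region led by Gngt1, Pde6a and Nr2e3 held 26.1 ± 6.19% of clustered spots (n = 4 frames), and a ganglion region led by Pou4f1, Slc17a6, Nefl and Sncg held 22.6 ± 2.82%. The ganglion region joined a cluster of 300 spots led by Pou4f1 and Slc17a6 and a cluster of 343 spots led by Nefl and Sncg. In the latter the highest fold was 3.34, and its leading genes included the inner nuclear panel genes Tfap2b, Slc32a1, Onecut2 and Pax6. An inner nuclear region led by the bipolar genes Grm6 and Cabp5 held 18.1 ± 5.74%. The outer coat of the eye formed a fibrous region led by Dcn, Col1a2 and Col1a1 with 13.3 ± 3.58% and a pigmented region led by Lrat, Rpe65 and Dct with 10.7 ± 5.29%. Smaller regions were led by Mobp and Mbp (myelin, 2.93 ± 2.65%), Krt4, Krt15 and Krt5 (epithelium, 2.74 ± 1.03%), Myh4 and Tnnc2 (muscle, 1.96 ± 0.308%) and Hbb-bs and Hba-a2 (blood, 1.71 ± 0.798%). The myelin region had 15, 27 and 36 spots in frames 2, 3 and 4 and 0 of 743 in frame 1, where up to 0.404% of clustered spots remains possible. Of all spots over tissue, 37.5 ± 7.07% had too few panel UMIs to be placed. Region shares depend on the clustering: the photoreceptor share was 42.0% with k-means and the ganglion share 11.2%.

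**Figure D1:**
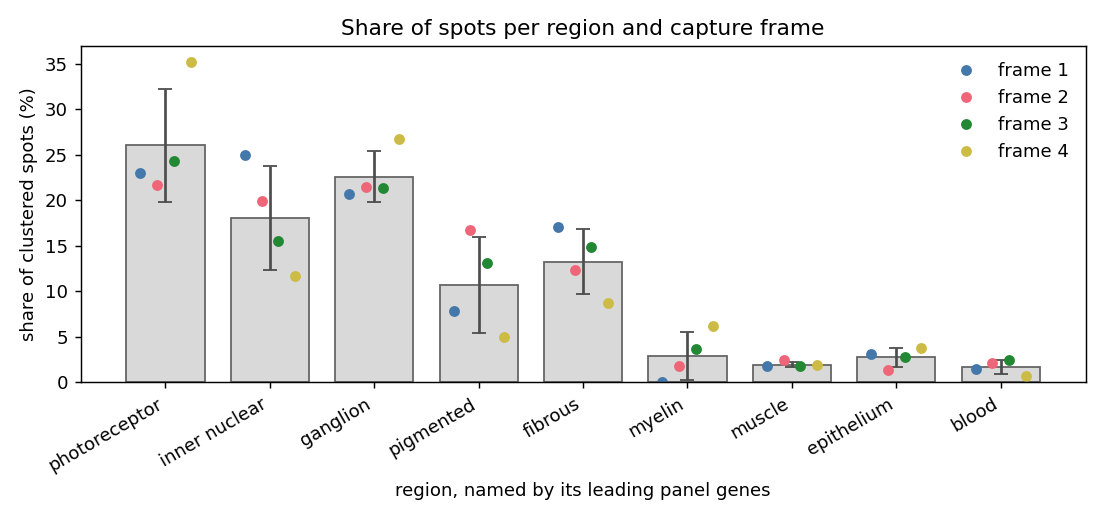
Share of clustered spots in each region, with bars for the mean of 4 frames, error bars for the SD and points for single frames. The photoreceptor region was the largest on average at 26.1%, and the myelin region was absent from frame 1 and reached 6.19% in frame 4.

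Wif1 itself was scarce, at 15.8 ± 9.52 CPM across frames (n = 4), with 58 UMIs in 41 spots. Of these, 35 UMIs fell in 21 of 643 ganglion spots, where the pooled level was 42.6 CPM (95% counting interval 29.7 to 59.2), and UMIs were present there in 4 of 4 frames. Over frames the ganglion level was 38.55 ± 39.63 CPM (10.75, 97.3, 21.2 and 25.0 in frames 1 to 4). Counting intervals treat UMIs as independent and leave out this spread between frames. The inner nuclear region held 10 UMIs (15.3 CPM, interval 7.36 to 28.2), whereas 0 were found in 732 photoreceptor spots (interval up to 5.57 CPM) and 0 in the fibrous region (interval up to 8.64 CPM). Against a floor of 3 UMIs over the photoreceptor region, the ganglion level was at least 9.40-fold higher, and at least 5.93-fold higher without the spot that held 13 of its UMIs. Frame 2 supplied 24 of the 35 ganglion UMIs, and without this frame the ganglion level was at least 3.13-fold higher. These folds leave out counting error of the ganglion UMIs, so they are not 95% limits. Wif1 had too few counts for a test of regions, as did Axin2 and Lef1, both switched on by Wnt signalling. Lef1 had at most 6 UMIs in a region.

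Levels of other Wnt antagonists and feedback inhibitors were highest in the coat among the 5 larger regions. The sum of the 23 genes of this list was 1373 ± 459.7 CPM in the pigmented region, 594 ± 65.8 in the fibrous, 435 ± 87.3 in the inner nuclear, 264 ± 74.7 in the ganglion and 141 ± 27.4 in the photoreceptor region (n = 4 frames each). Dkk3, a member of the Dickkopf family of Wnt modulators, had 694 ± 362 CPM in the pigmented region and 33.5 ± 22.8 in the photoreceptor region. Sfrp1, which binds Wnt proteins outside the cell, had 348 ± 90.8 and 12.6 ± 8.55 CPM in the same 2 regions. Tcf4, a basic helix-loop-helix transcription factor gene named in the study design, stood at 149 ± 10.7 CPM across frames and was highest in the inner nuclear region among the 5 larger regions (265 ± 24.6). The gene Tcf7l2, whose protein is often called TCF4 in work on Wnt signalling, is a different gene. Ctnnb1, which encodes beta-catenin, had 156 ± 7.95 CPM across frames. Wnt ligand and secretion genes summed to 118 ± 60.2 CPM in the pigmented region and 22.5 in the photoreceptor region, and 0 of the 26 genes of this list had enough counts for a test in any comparison.

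**Figure D2:**
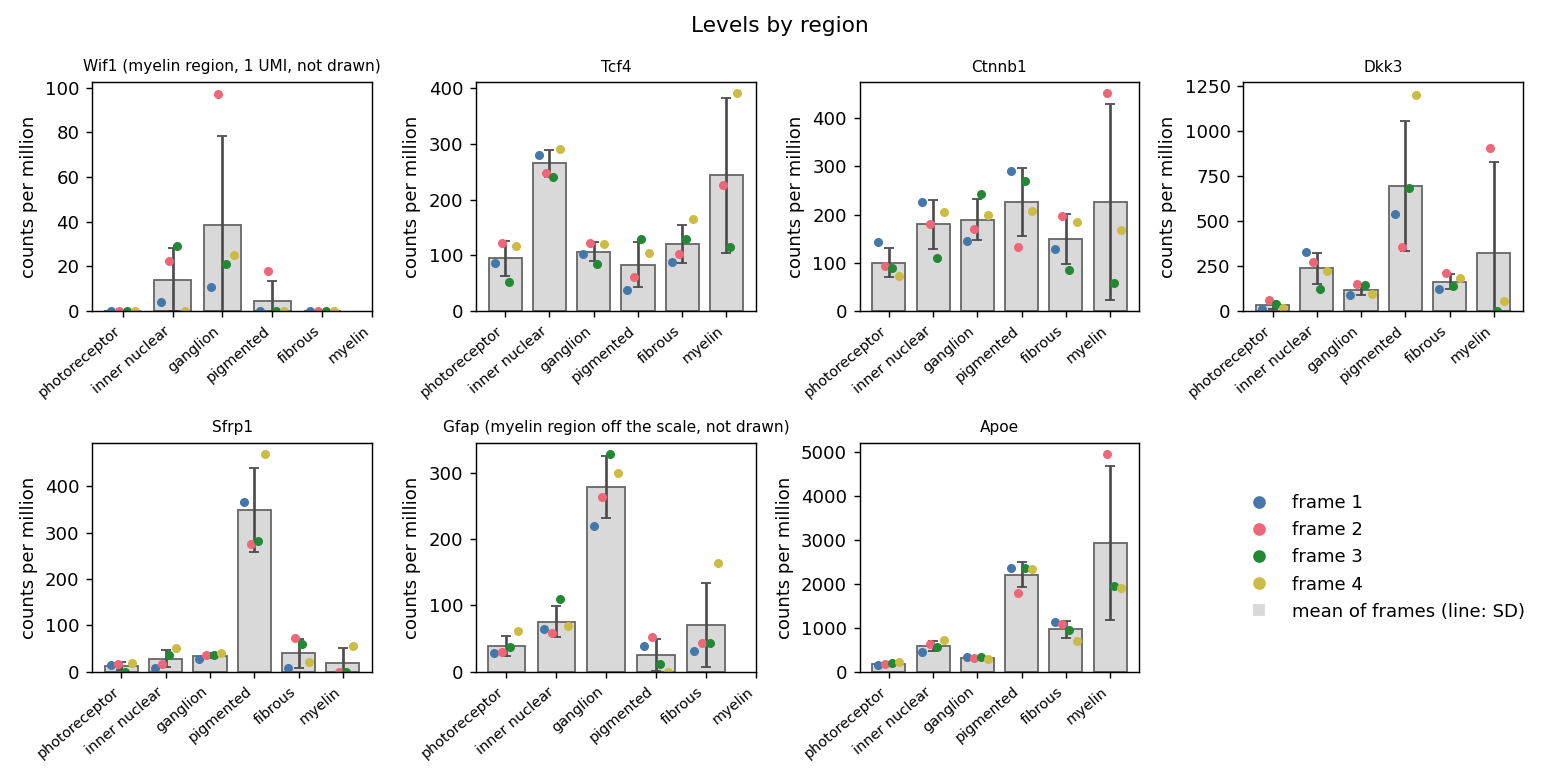
CPM of Wif1, Tcf4, Ctnnb1, Dkk3, Sfrp1, Gfap and Apoe in the larger regions, with bars for the mean over frames, error bars for the SD and points for single frames. Among the 5 larger regions Tcf4 peaked in the inner nuclear region (265 CPM), Dkk3 and Sfrp1 in the pigmented region (694 and 348 CPM). The myelin values of Wif1 and Gfap are not drawn.

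The inner retina, made of the inner nuclear and ganglion regions, carried more RNA of neuronal cytoskeleton and axon genes, and less of phototransduction genes, than the photoreceptor region. These 2 lists did not pass camera with an estimated correlation (adjusted p = 0.431 for each). Photoreceptor and ganglion panel genes, neurofilament genes among them, drew these regions. Differences in genes related to them were therefore largely built in, whatever their p-values. Dpysl2, which steers growing axons, stood at 2308 ± 208 against 276 ± 58.5 CPM (n = 4 frames), a log2 fold of 2.91 ± 0.371. It was higher in 4 of 4 frames (edgeR quasi-likelihood test with Benjamini-Hochberg adjusted p = 5.71e-26). The release gene Snap25 had 5811 ± 693 against 1583 ± 318 CPM (log2 fold 1.74 ± 0.425). Rbp3, which carries retinoids between photoreceptors and pigment epithelium, fell to 495 ± 84.9 from 2888 ± 397 CPM (log2 fold -2.68 ± 0.434, lower in 4 of 4 frames). In total 1615 of 3278 genes passed, 885 higher and 730 lower (54.8% higher, and 71.7% higher without the filter on low counts).

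The largest folds toward the inner retina were in genes almost absent from photoreceptors. Ypel4, a gene of the Yippee family, had 160 UMIs against 1 (ratio 71.9, interval 12.7 to 2858), Rnd3, a regulator of the actin skeleton, 148 against 1 (66.5, 11.8 to 2645), and the synaptic vesicle gene Rab3c 206 against 2 (46.3, 12.7 to 384.9). Tagln3, Hunk and Prkar1b, all known from neurons, had 2 UMIs each in the photoreceptor region, with ratios of 34.4 (9.36 to 286.5), 33.3 (9.05 to 277.2) and 32.6 (8.86 to 271.7). Trarg1, a trafficking regulator of the glucose transporter, rose by a log2 fold of 4.85 ± 1.12, the neurite growth gene Nrn1 by 4.75 ± 1.04, the endosome gene Nsg1 by 4.73 ± 0.443 and the migration gene Elmo1 by 4.59 ± 0.837 (n = 4 frames, higher in 4 of 4). Toward photoreceptors, the hexokinase gene Hk2, which starts glycolysis, was lower in the inner retina (-2.59 ± 0.491). The lipid carrier gene Fabp12 (-2.68 ± 0.208), the potassium channel gene Kcnj14 (-2.65 ± 0.517), the transcript AI847159 (-2.64 ± 0.325), the disc protein gene Prcd (-2.55 ± 0.66), Lrrc2 (-2.53 ± 0.43), the chromatin gene Mta2 (-2.53 ± 0.484) and the retinal protein gene Rtbdn (-2.52 ± 0.12) were also lower in 4 of 4 frames.

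Of 22 neuronal cytoskeleton and axon genes, 17 were higher in the inner retina, 3 lower and 2 did not pass, with Stmn4 at a log2 fold of 3.19 ± 0.767 and Crmp1 at 2.64 ± 0.471. This list moved against other genes (camera adjusted p = 6.21e-08, but adjusted p = 0.431 with an estimated correlation) and on balance 1 way (fry adjusted p = 0.0062). Phototransduction genes outside the panel went the other way, 23 of 25 lower, 1 higher and 1 not passing, with the exchanger gene Slc24a1 at -2.50 ± 0.256 and the cyclase activator gene Guca1b at -2.38 ± 0.301. Their list had a camera adjusted p = 9.24e-30 (adjusted p = 0.431 with an estimated correlation). Synaptic genes divided, with 11 of 22 higher and 5 lower, among the latter Cplx4 (-2.34 ± 0.346) and Slc17a7 (-2.15 ± 0.142). Interneuron receptor genes rose in 5 of 6 and fell in 1, including Grin1 (3.03 ± 0.399) and Gabrr1 (2.32 ± 0.567), with camera adjusted p = 0.0338 (adjusted p = 0.525 with an estimated correlation). This camera call ended in 6 of 13 other settings, the estimated correlation among them, and in 1 of 4 fits with a frame left out.

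Many glial and immune genes also differed. Of 10 gliosis genes 6 rose in the inner retina, 1 fell and 3 did not pass, and the list did not pass camera (adjusted p = 0.0628), with the iron-binding gene Lcn2 at 2.49 ± 0.947, Spc25 at 2.67 ± 0.631 and Gfap at 2.19 ± 0.269 (196 ± 55.1 against 39.1 ± 15.2 CPM, n = 4). Apoe rose by 1.02 ± 0.316. Microglia and complement genes rose in 5 of 6, with B2m, which carries class I antigens, at 2.19 ± 0.647, C3 at 2.05 ± 1.09 and Tyrobp at 1.75 ± 0.411 (camera adjusted p = 0.0338, and adjusted p = 0.525 with an estimated correlation). The camera call of this list ended in 9 of 13 other settings, the estimated correlation among them, and in 1 of 4 fits with a frame left out. The 3 immunoglobulin and leukocyte genes all rose, Igkc by 3.08 ± 0.556, Ptprc by 2.02 ± 0.605 and Jchain by 2.34 ± 0.851 (camera adjusted p = 0.00271, and adjusted p = 0.452 with an estimated correlation). The 2 tested endothelium and mural genes rose, the pericyte gene Rgs5 by 3.29 ± 0.803 and the clotting gene Vwf by 1.51 ± 0.776.

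Genes of energy and lipid metabolism went both ways. Of 66 nuclear oxidative phosphorylation genes 12 were lower, 1 higher and 53 did not pass, with Ndufa4 at -1.16 ± 0.268, Atp5h at -0.69 ± 0.263 and Atp5e at -0.86 ± 0.153. Of 13 mitochondrially encoded genes 6 were lower and 0 higher, among them mt-Cytb (-0.62 ± 0.272), mt-Nd3 (-0.63 ± 0.401) and mt-Co2 (-0.36 ± 0.288). Glycolysis genes were split, 9 of 20 higher and 6 lower, where Hk1 (-1.503 ± 0.234) and the lactate carrier gene Slc16a1 (-1.56 ± 0.207) were lower; the list's median was positive (0.23) although its camera direction was down. Of 7 sterol and fatty acid genes 4 rose and 1 fell. Among those that rose was Insig1 (2.50 ± 0.786), and Elovl4, which makes the very long fatty acids of outer segments, fell (-2.15 ± 0.306). Genes of the visual cycle and pigment epithelium list were lower in 5 of 8, with Cst3 at -0.97 ± 0.127, Ptgds at -1.05 ± 0.507 and Otx2 at -1.34 ± 1.03 (camera adjusted p = 0.0338, and adjusted p = 0.452 with an estimated correlation). Neuronal injury genes were lower in 3 of 5 (Map3k12 -1.09 ± 0.213, Hspa5 -0.82 ± 0.355, Gadd45a -1.02 ± 0.225), and of 2 immediate early genes Btg2 was lower (-1.15 ± 0.731).

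Among Wnt genes, Dkk3 rose in the inner retina by 2.17 ± 0.842, while the coreceptor gene Lrp6 (-1.31 ± 0.367) and the receptor gene Ryk (-0.66 ± 0.211) were lower, 2 of 3 tested receptors (n = 4 frames). Of 9 genes of the intracellular pathway list 2 rose: Ctnnb1 by 0.78 ± 0.399 and Tcf4 by 0.75 ± 0.486 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.013 and 0.0233, higher in 4 of 4 frames). Tcf4 was on that fixed list, but it is not Tcf7l2, so its fold is not read as a Wnt pathway result. The 1 tested Wnt target gene, Jun, did not pass. Glaucoma-associated genes rose in 3 of 6, with the axon survival gene Nmnat2 at 108 UMIs against 1 (ratio 48.55, interval 8.53 to 1935), Tgfb2 at 2.25 ± 0.584 and Foxc1 at 1.33 ± 1.40 (higher in 3 of 4 frames). Matrix genes were mixed, 2 of 8 higher and 1 lower, with Lamb2 at 2.18 ± 0.516, Timp2 at 1.14 ± 0.312 and Vtn at -2.13 ± 0.598; the median of the list was positive (0.36) while its camera direction was down. Adjusted over the list alone, the counts differed only for oxidative phosphorylation (1 higher, 5 lower) and phototransduction (24 lower). Ctnnb1 and Tcf4 did not pass under DESeq2 (0.80 and 0.77) or with regions from a random 50% of the UMIs (0.61 and 0.68, where Apoe was -0.29), Tcf4 did not pass with k-means (0.24), at Leiden resolution 1, at 50 or 10 panel UMIs or without frame 1 (0.65) or 3 (0.59), and Ctnnb1 did not pass without frame 3 (0.75) or 4 (0.63). Gadd45a did not pass under DESeq2 (-1.03), without the filter or with any 1 frame left out. Hspa5 did not pass without the filter or frame 4 (-0.68). Foxc1 did not pass in 5 of 10 other settings or in 2 of 4 fits with a frame left out.

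The outer coat, made of the pigmented and fibrous regions, was set apart from the neural retina by visual cycle, pigment epithelium and matrix genes. Pigmented and fibrous panel genes drew the coat, so differences in genes related to them were largely built in, whatever their p-values. Their 2 lists outside the panel did not pass camera with an estimated correlation (adjusted p = 0.0759 for each). Ptgds, which makes prostaglandin D2 and carries retinoids, reached 7489 ± 1200 against 859 ± 295 CPM (log2 fold 3.28 ± 0.356, n = 4 frames, higher in 4 of 4, edgeR quasi-likelihood test with Benjamini-Hochberg adjusted p = 9.8e-14). The gap junction gene Gja1 had 1295 ± 404 against 127 ± 38.4 CPM (3.44 ± 0.329), and the matrix gene Timp3, mutated in Sorsby fundus dystrophy, 781 ± 192 against 97.7 ± 19.0 CPM (3.09 ± 0.404). Snap25 fell to 1070.0 ± 92.4 from 4435 ± 362 CPM (-1.95 ± 0.0525). In total 976 of 4720 genes passed, 479 higher and 497 lower in the coat (49.1% higher, and 36.1% higher without the filter on low counts).

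The largest folds toward the coat were the secreted peroxidase gene Gpx3 (4.26 ± 1.02), the melanosome genes Gpnmb (4.15 ± 0.0814) and Oca2 (3.54 ± 0.502), and Tgfbr3, a coreceptor for TGF-beta (3.55 ± 0.472). Next came the matrix genes Sned1 (3.43 ± 0.605) and Fbln1 (3.34 ± 0.902), Myoc, mutated in open-angle glaucoma (3.42 ± 0.68), the bicarbonate transporter gene Slc4a5 (3.38 ± 0.667) and the liprin gene Ppfibp2 (3.38 ± 0.507), each higher in 4 of 4 frames. The largest in the other direction were Nrn1 (-3.99 ± 0.667, 8.93 against 159 CPM), the channel gene Kcnh7 (-3.55 ± 0.984), the cytokine subunit gene Il12a (-3.39 ± 1.06) and the receptor partner gene Cacng2 (-3.16 ± 1.05). They were followed by Ube2ql1 (-3.09 ± 1.16), the ion pump partner gene Fxyd7 (-3.03 ± 0.467), the zinc transporter gene Tmem163 (-2.998 ± 1.22), the calcium-binding gene Calb2 (-2.995 ± 0.589), Nsg2 (-2.97 ± 0.367) and Rasgrf1 (-2.83 ± 0.548), each lower in 4 of 4 frames.

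All 3 tested genes of the list of Wnt antagonists and feedback inhibitors were higher in the coat: Sfrp1 by 2.71 ± 0.286 (145 ± 21.9 against 24.4 ± 7.02 CPM), Sfrp2 by 2.70 ± 0.455 and Dkk3 by 1.41 ± 0.893 (n = 4 frames, higher in 4 of 4, edgeR quasi-likelihood with Benjamini-Hochberg adjusted p = 1.77e-06, 3.82e-07 and 0.000476). Their list moved against other genes (camera adjusted p = 1.28e-06, and adjusted p = 0.0759 with an estimated correlation). For Sfrp1 and Dkk3 the rise came mostly from the pigmented region. Fibrous Sfrp1 had 8.02, 72.8, 60.2 and 20.6 CPM in frames 1 to 4, against 26.9 to 39.9 in the ganglion region. Fibrous Dkk3 had 120, 211, 138 and 185 CPM, below the inner nuclear region in frames 1, 2 and 4 (328, 275 and 223 CPM). Of 4 Wnt target genes 3 rose, Bmp4 by 3.34 ± 0.394, Sox9 by 2.10 ± 1.16 and Id2 by 1.69 ± 0.418 (camera adjusted p = 0.00907, and adjusted p = 0.296 with an estimated correlation). Of 4 receptors Ryk (1.08 ± 0.181) and Lgr4 (0.76 ± 0.296) rose and 2 did not pass. Of 15 intracellular pathway genes 0 passed edgeR's quasi-likelihood test, and 2 had an unadjusted p below 0.05, the kinase gene Gsk3b (-0.39 ± 0.0999) and the destruction complex gene Apc (-0.81 ± 0.31). Tcf4 (-0.42 ± 0.657) and Ctnnb1 (0.23 ± 0.112) did not pass, with adjusted p = 0.333 and 0.538.

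Matrix genes outside the panel rose in 15 of 18 with 0 lower, including Igfbp5 (2.44 ± 0.371) and the proteoglycan gene Bgn (2.88 ± 0.501), at camera adjusted p = 7.62e-22 (adjusted p = 0.0759 with an estimated correlation). All 15 visual cycle and pigment epithelium genes rose, with the iron carrier gene Trf at 2.66 ± 0.628 and the retinol dehydrogenase gene Rdh10 at 2.45 ± 0.695 (camera adjusted p = 3.37e-33, and adjusted p = 0.0759 with an estimated correlation). Of 16 gliosis genes 9 rose, 2 fell and 5 did not pass: Apoe rose by 2.09 ± 0.193, the metallothionein gene Mt2 by 2.07 ± 0.435 and Serpina3n by 2.78 ± 0.603, whereas Gfap fell (-1.43 ± 0.668, lower in 4 of 4 frames). The gliosis list had camera adjusted p = 6.14e-08 (adjusted p = 0.0759 with an estimated correlation). Microglia and complement genes rose in 9 of 13 with 0 lower, including the lysosomal genes Ctsd (2.05 ± 0.192) and Lyz2 (2.14 ± 1.10) and the complement inhibitor gene Serping1 (2.26 ± 0.904), at camera adjusted p = 8.14e-09 (adjusted p = 0.296 with an estimated correlation). Of 6 endothelium and mural genes 3 rose, Myh11 by 2.30 ± 0.928, Vwf by 1.31 ± 0.457 and Acta2 by 1.79 ± 1.16 (camera adjusted p = 0.0273, and adjusted p = 0.536 with an estimated correlation).

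Neuronal lists were lower in the coat. Of 22 cytoskeleton and axon genes 16 fell and 0 rose, with Dpysl2 at -1.59 ± 0.183, Crmp1 at -2.25 ± 0.502 and Stmn4 at -1.88 ± 0.429 (camera adjusted p = 7.21e-12, and adjusted p = 0.0759 with an estimated correlation). Of 23 synaptic genes 14 fell and 1 rose, with the release genes Cplx1 at -2.42 ± 0.364 and Vamp1 at -3.04 ± 1.08 (camera adjusted p = 2.09e-05, and adjusted p = 0.296 with an estimated correlation). Interneuron genes fell in 7 of 10, but the enkephalin gene Penk rose (2.90 ± 0.655). Their camera adjusted p was 0.0273 (adjusted p = 0.296 with an estimated correlation). This call ended in 9 of 14 other settings, the estimated correlation among them, and in 1 of 4 fits with a frame left out. Most phototransduction genes did not pass (23 of 26), with Slc24a2 lower (-2.002 ± 0.29) and Rbp3 (0.43 ± 0.306) and Aipl1 (0.32 ± 0.348) higher. Coat spots carried much photoreceptor RNA: phototransduction genes outside the panel summed to 36090 CPM in the fibrous region, above the 26770 of the inner nuclear region, and 194 of 709 coat spots had more than 5% photoreceptor panel UMIs. In the other coat spots, a choice made after seeing the data that by itself lowers such genes, Rbp3 was -0.77 and Aipl1 -0.12.

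Metabolic lists were mixed in the coat. Of 74 nuclear oxidative phosphorylation genes 8 rose and 0 fell, with Cox6b1 at 1.07 ± 0.264, Atp5j2 at 0.79 ± 0.103 and Atp5e at 0.72 ± 0.441 (camera adjusted p = 0.03, and adjusted p = 0.536 with an estimated correlation). The camera call of this list ended in 7 of 14 other settings, the estimated correlation among them, and in 2 of 4 fits with a frame left out. Of 13 mitochondrially encoded genes 2 fell, mt-Nd1 (-0.30 ± 0.155) and mt-Nd4l (-0.86 ± 0.3). Glycolysis genes rose in 4 of 21 and fell in 5, with the glucose transporter gene Slc2a1 at 1.06 ± 0.295, Bsg at 0.82 ± 0.197 and the lactate carrier gene Slc16a8 at 2.98 ± 0.898. Of 16 sterol genes 1 fell, Hmgcs1 (-1.44 ± 0.287). Of 5 injury genes 1 rose, the chaperone gene Hspa5 (0.81 ± 0.162), and 0 of 4 immediate early genes passed edgeR's quasi-likelihood test, with 0 at an unadjusted p below 0.05. Glaucoma-associated genes rose in 3 of 12: Myoc, Efemp1 by 2.16 ± 1.23 and Foxc1 by 1.37 ± 1.14. Efemp1 and Foxc1 were higher in 3 of 4 frames. Of 3 immunoglobulin and leukocyte genes in the coat, Igkc (0.62 ± 0.479) and Jchain (0.86 ± 1.02) rose.

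Adjusted over the list alone, the coat counts became 16 higher for matrix, 3 higher and 1 lower for glaucoma, 10 and 2 for gliosis, 4 and 7 for glycolysis and 10 and 0 for microglia. They became 0 and 0 for mitochondrially encoded genes, 1 and 18 for cytoskeleton, 1 and 0 for oxidative phosphorylation and 3 and 15 for synaptic genes, and were unchanged for the other lists. Rbp3 and Aipl1 did not pass under DESeq2 (0.41 and 0.30), without the replicate block (0.43 and 0.28) or without frame 1 or 2, and turned to -1.15 and -0.36 at Leiden resolution 0.3. Of 14 other settings and 4 left-out frames together, Atp5j2 did not pass in 10, Atp5e in 8 and Hspa5 in 5, and mt-Nd1 did not pass in 10 of 13 settings and 4 frames. Gfap did not pass with regions from a random 50% of the UMIs (-0.40), without a ganglion cluster of low folds (-0.89) or at 50 panel UMIs (-1.17). Lgr4 and mt-Nd4l did not pass with any 1 frame left out, Igkc (0.30) and Jchain (0.33) did not pass without frame 3 or without the replicate block (0.80 and 1.17), and without frame 2 the number of genes was 569.

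The ganglion region had more RNA of cytoskeleton and axon genes than the inner nuclear region and less of phototransduction genes. These 2 lists did not pass camera with an estimated correlation (adjusted p = 0.189 and 0.218). Since panel genes of ganglion cells and photoreceptors helped to draw the regions, differences in related genes were largely built in. Tmem163, a zinc transporter gene, stood at 1017 ± 79.5 against 97.0 CPM (log2 fold 3.32 ± 0.0914, n = 4 frames, higher in 4 of 4, edgeR quasi-likelihood test with Benjamini-Hochberg adjusted p = 1.09e-10), and Calb2, which encodes the calcium buffer calretinin, at 696 ± 63.4 against 109 ± 36.9 CPM (2.60 ± 0.333). Tcf4 was lower in the ganglion region, 107 ± 17.3 against 265 ± 24.6 CPM (-1.36 ± 0.215, lower in 4 of 4 frames, adjusted p = 0.000352). Gfap was higher, 278 ± 46.6 against 75.2 ± 23.3 CPM (1.82 ± 0.233). In total 913 of 3214 genes passed, 468 higher and 445 lower (51.3% higher, and 61.3% higher without the filter on low counts).

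Other large folds toward the ganglion region were Fars2, a mitochondrial tRNA synthetase gene (3.16 ± 0.603), the glycosyltransferase gene Galnt9 (3.14 ± 0.52), the synaptic adhesion gene Clstn2 (3.01 ± 0.774), the release gene Cplx1 (2.87 ± 0.334), Nrn1 (2.83 ± 0.734), Il12a (2.68 ± 0.263) and Vamp1 (2.53 ± 1.30), each higher in 4 of 4 frames. The antibody chain gene Ighg2c was also higher (2.90 ± 0.397), with 275 UMIs against 29. Toward the inner nuclear region the largest folds were in photoreceptor genes, and its spots held 26770 CPM of phototransduction genes against 6041 in the ganglion region. Among these genes were the disc genes Prom1 (-3.57 ± 0.891) and Prcd (-3.36), the matrix gene Impg2 (-3.54 ± 1.30) and the glutamate carrier gene Slc17a7 (-3.47 ± 0.721). Kcnj14 (-3.32 ± 1.28), the trafficking gene Reep6 (-3.28 ± 0.297), the retinal reductase gene Rdh12 (-3.27 ± 0.41), Rgs9bp (-3.22 ± 0.466) and Rbp3 (-3.19 ± 0.715) followed, each lower in 4 of 4 frames.

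Of 22 cytoskeleton and axon genes 14 were higher in the ganglion region, 1 lower and 7 did not pass, with Stmn4 at 1.49 ± 0.499 and the axonal motor gene Kif5a at 2.01 ± 0.435 (camera adjusted p = 1.02e-06, and adjusted p = 0.189 with an estimated correlation). Phototransduction genes fell in 22 of 23 and rose in 1, with Slc24a1 at -2.82 ± 0.628, Aipl1 at -2.14 ± 0.51 and Gnb1 at -1.79 ± 0.254 (camera adjusted p = 6.91e-37, and adjusted p = 0.218 with an estimated correlation). Synaptic genes rose in 8 of 22 and fell in 5: Snap25 rose by 1.26 ± 0.348 (7605 ± 446 against 3066 ± 790 CPM) and Cplx4 fell (-2.75 ± 0.838). Of 8 genes tested from the interneuron list 2 fell, the dopamine receptor gene Drd4 (-3.34 ± 0.808) and the bipolar GABA receptor gene Gabrr1 (-2.20 ± 1.64, lower in 3 of 4 frames). Genes of the visual cycle and pigment epithelium list fell in 5 of 8, including Otx2 (-2.22 ± 0.258), Ptgds (-1.13 ± 0.528) and Trf (-1.65 ± 0.852), with camera adjusted p = 0.0119 (adjusted p = 0.665 with an estimated correlation).

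Of 9 gliosis genes 3 rose and 5 fell: beside Gfap, the glutamate uptake gene Slc1a2 (-2.42 ± 0.733) and Apoe (-0.92 ± 0.447) fell. Microglia genes rose in 3 of 7, B2m by 0.76 ± 0.347, Ctss by 1.03 ± 0.589 and Tyrobp by 0.89 ± 0.348, and of 3 immunoglobulin and leukocyte genes Igkc (1.503 ± 0.899) and Ptprc (1.18 ± 0.588) rose. Of 4 endothelium and mural genes 3 rose, Rgs5 by 0.97 ± 0.484, Vwf by 0.90 ± 0.599 and Myh11 by 1.49 ± 1.61 (higher in 3 of 4 frames). Matrix genes fell in 3 of 7, Vtn (-2.37 ± 1.03), Timp3 (-1.27 ± 0.417) and Lamb2 (-1.39 ± 1.18). Vtn was also lower in the inner retina than in the photoreceptor region, so its fold may follow photoreceptor RNA in inner nuclear spots. Among genes of the Wnt lists, Dkk3 fell (-1.01 ± 0.787, lower in 3 of 4 frames), Ryk fell as 1 of 3 receptors (-0.50 ± 0.381), and the 1 tested target gene, Jun, did not pass. Of 9 genes of the intracellular pathway list Tcf4 fell and 8 did not pass. Tcf4 is not Tcf7l2, so its fold is not read as a Wnt pathway result. Ctnnb1 was level (189.6 ± 42.3 against 180.4 ± 50.7 CPM, adjusted p = 0.999).

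Glycolysis genes were evenly divided between these 2 inner regions, 6 of 20 higher and 6 lower in the ganglion region. Examples are the lactate dehydrogenase gene Ldhb at 1.63 ± 0.57, Hk2 at -3.04 ± 0.974 and Slc16a1 at -1.62 ± 0.76. Oxidative phosphorylation changed little, 1 of 64 higher (Cox7b, 0.91 ± 0.368) and 2 lower (Ndufa4, -0.47 ± 0.206, and Atp5e, -0.82 ± 0.307). In addition, 3 of 13 mitochondrially encoded genes fell: mt-Cytb (-0.53 ± 0.347), mt-Nd4 (-0.38 ± 0.287) and mt-Nd6 (-0.78 ± 0.291). Of 8 sterol genes 2 rose, among them Hmgcs1 (0.93 ± 0.9), and Elovl4 fell (-2.35 ± 0.561). Hk2, Slc16a1 and Elovl4 were also lower in the inner retina than in the photoreceptor region. Their folds here may follow photoreceptor RNA in inner nuclear spots, which was not tested. Of 7 glaucoma-associated genes Nmnat2 rose (1.35 ± 0.934) and Tgfb2 fell (-1.84 ± 0.513); the list's median was positive (0.46) and its mean negative (-0.04), with a camera direction of down. Hspa5 was the 1 of 4 injury genes that fell (-0.85 ± 0.416), and Btg2 the 1 of 3 immediate early genes (-1.34 ± 0.321), a list with a median of 0.07, a mean of -0.39 and a camera direction of down. Adjusted over the list alone, the counts became 15 higher and 1 lower for cytoskeleton, 9 and 5 for synaptic and 7 and 6 for glycolysis. They became 3 and 1 for microglia, 0 and 2 for injury, 1 and 1 for oxidative phosphorylation, 0 and 7 for visual cycle and 0 and 2 for Wnt receptors, and were unchanged elsewhere. Immune, vascular and Gfap folds depend on how the regions were drawn: with k-means Ighg2c was -1.09, Ptprc -0.67, Vwf -1.33 and Gfap -0.18, 313 genes passed with k-means and 601 without frame 3. Igkc did not pass without the replicate block (1.26) or without frame 4 (1.52). Dkk3 did not pass without the filter (-0.84), with regions from a random 50% of the UMIs (-0.75) or without frame 1 (-0.68). Ryk did not pass in 6 of 13 other settings or in 3 of 4 frames left out, Hspa5, mt-Nd4 and Tyrobp did not pass with any 1 frame left out, and Hspa5, mt-Nd4, mt-Nd6 and Atp5e did not pass in most other settings.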

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

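The tests chosen only after the result was seen are the splits of the region sums, the depth of the Wif1 spot, and the chi-square and myelin tests of Gfap between frames; all results of the myelin comparison and the low-fold ganglion cluster are also of this kind. In 244 groups of 4 frame values, a frame far from the other 3 by Dixon's test at 0.05 would be met by chance in about 1 in 20 groups, or 12.2, and 15 were met. This number gives no reason to treat the 15 as more than chance.

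In the share of spots, the ganglion region of frame 4 (26.8%) lay apart from the other 3 frames (20.7%, 21.5% and 21.4%), with a gap over range of 0.873. In the inner retina against the photoreceptor region, the same was met for Hunk (0.911), Mta2 (0.872), Atp5h (0.917), Tgfb2 (0.849) and Jchain (0.834). In the coat against the neural retina it was met for Ryk (0.970), Efemp1 (0.909), Sfrp1 (0.899), Sned1 (0.880), Cox6b1 (0.870), Vwf (0.870), Igfbp5 (0.857) and Igkc (0.834). Efemp1 is the 1 of these with a frame of the opposite sign, at -0.255 (prior count 2) in frame 4. In the ganglion against the inner nuclear region it was met for Otx2 (0.854).

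When the region sums of a comparison were split in other ways, the real labels gave 1615 genes for the inner retina, 976 for the coat and 913 for ganglion against inner nuclear, and the highest other split gave 0 in each. The real labels were 1 of 32 splits in each, a share under 0.05, but most of these splits do not keep the regions of a frame apart. Of the 8 splits that part every frame the real one was again the 1 with as many genes, and 8 are too few for a share under 0.05. Since the regions were drawn from expression in the same spots, mixed labels were bound to give few genes, so the splits say little about chance. For the myelin comparison, 1 of 10 splits, the real one, gave 345 genes and the highest other gave 0, and 10 splits are too few for a share under 0.05.

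Wif1 had 8 UMIs in 7 of 1725 spots outside all regions, where 0 UMIs would allow up to 3. Of all 58 Wif1 UMIs, 13 (22.4%) lay in 1 ganglion spot of frame 2 that had 2434 UMIs, and the next highest spot had 3. The depth of the spot does not account for this, since its share of the frame's UMIs gives an expected 0.0707 Wif1 UMIs (Poisson probability of as many 1.67e-25 in a single spot). Nor is such gathering common among genes of like abundance: 1.15% of 2781 genes with 40 to 80 UMIs held as large a share in 1 spot, against a median share of 5.88%. What stays open is a local source of Wif1 RNA, which may be 1 or a few cells of high Wif1 RNA, or a fault of that spot. No biological explanation was tested, since all frames carry the same label, and vector RNA was not measured separately from the mouse gene.

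Gfap differed between frames, from 98.2 CPM in frame 1 to 344 in frame 3, a ratio of 3.51. Counting intervals of these 2 frames (78.8 to 121 and 307 to 385 CPM) lie apart, but separate sections often differ by more than counting noise, so a chi-square test over the 4 frames (p = 1.51e-33) says little. A comparison with other genes says more: 0.455% of 1100 genes with 50% to 200% of the Gfap UMIs had as high a ratio, with a median of 1.39, so neither counting error nor a spread shared by genes of like abundance accounts for the difference. Without myelin spots, of which frame 1 had 0, the ratio was 2.02, so the amount of myelin region on the frame may explain part of the difference. Within the ganglion region alone the ratio was 1.49. No biological explanation was tested.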

How the results depend on the processing

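The alternatives chosen only after the result was seen are those without the low-fold ganglion cluster (343 of the ganglion spots, whose leading genes had low folds), the coat spots with at most 5% photoreceptor panel UMIs, and everything in the myelin comparison. The comparisons gave 1615 (885 higher, 730 lower) genes for the inner retina, 976 (479, 497) for the coat, 913 (468, 445) for ganglion against inner nuclear and 345 (145, 200) for myelin against ganglion.

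Without a filter on low counts, 1713 genes were higher in the inner retina, 810 lower in the coat and 40 higher in the myelin region. At 50 panel UMIs, 538 genes passed in the coat (245 higher, 293 lower) and 448 in the ganglion comparison (238, 210). At 10 panel UMIs, 527 (275, 252) passed in the ganglion comparison. With regions from a random 50% of the UMIs, 395 (219, 176) passed in the coat, 541 (282, 259) in the ganglion comparison, and 94 were higher in the myelin region. Shared with the main calls were 976 of 1615 (60.4%) in the inner retina, 291 of 976 (29.8%) in the coat, 451 of 913 (49.4%) in the ganglion comparison and 219 of 345 (63.5%) in the myelin comparison. With the random 50%, a cluster of 437 spots tied between the muscle and pigmented classes and stayed unnamed. The coat then held 91 spots in frame 2 against 241 in the main setting. Its counts, shared calls and sign changes in that setting therefore compare partly other tissue. The inner nuclear region held 158 spots in frame 4 with the random 50%, against 68 in the main setting. The inner retina and ganglion comparisons with the random 50% thus also used partly other spots. The ganglion comparison gave 397 (193, 204) at Leiden resolution 0.3 and 313 (154, 159) with k-means, of which 325 and 245 were shared with the 913. Without the replicate block the myelin comparison gave 571, with 355 lower.

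Leaving out each frame gave 1423 to 1613 genes for the inner retina. For the coat it gave 569 (without frame 2) to 1066, with 277 to 534 higher and 292 to 532 lower. For ganglion against inner nuclear it gave 601 (without frame 3) to 881, with 311 to 465 higher and 290 to 416 lower. For the myelin comparison it gave 46 (without frame 3), 110 (without frame 4) and 247, with 38 to 116 higher and 8 to 131 lower.

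Some log2 folds changed sign. With regions from a random 50% of the UMIs, Apoe was -0.29 in the inner retina. In the coat, Rbp3 (-1.09), Aipl1 (-0.22), Atp5e (-0.35), mt-Nd1 (0.17), Trf (-0.13) and Tcf4 (0.24) changed sign in that setting, Rbp3 (-1.15), Aipl1 (-0.36) and Tcf4 (0.057) at Leiden 0.3, Rbp3 (-0.0094) with k-means, and Rbp3 (-0.77) and Aipl1 (-0.12) in coat spots with at most 5% photoreceptor panel UMIs. In the ganglion comparison at Leiden 0.3 the values were Ighg2c -0.38, B2m -0.32, Ctss -0.042, Tyrobp -0.44, Vwf -1.37 and Ptprc -0.51. With k-means they were Ighg2c -1.09, Gfap -0.18, B2m -0.33, Ctss -0.25, Tyrobp -0.47, Atp5e 0.049, Vwf -1.33, Igkc -0.010 and Ptprc -0.67. Vwf was -0.16 at 50 panel UMIs, -0.26 at 10, -0.56 with the random 50% and -0.0096 without the low-fold ganglion cluster.

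Ctnnb1 lay at -0.00091 in the ganglion comparison and did not pass, so its sign means little. It was 0.024 with DESeq2, 0.026 with plain library sizes and with panel genes in them, 0.17 without a filter, 0.00043 without mitochondrially encoded genes, 0.032 without the replicate block, 0.072 at 50 panel UMIs, 0.29 with the random 50% and 0.14 without the low-fold cluster. Leaving out each frame gave -0.29 to 0.27. In the myelin comparison, Dkk3 was -0.26 with DESeq2 and -1.02 without a filter, where mt-Nd1 was -0.27 and mt-Co2 -0.35. Ctnnb1 was 0.35 there with the random 50% and -0.85 to 0.12 with each frame left out.

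Mean shares of spots moved with the clustering. The photoreceptor share was 41.4% at Leiden 0.3, 42.0% with k-means and 39.6% at 50 panel UMIs, and the inner nuclear share 11.9% at 10 panel UMIs. The ganglion share was 13.2% at Leiden 0.3, 11.2% with k-means, 13.75% at 50 panel UMIs and 10.8% at 10. The pigmented share was 17.6% at Leiden 0.3 and 17.5% at 10 panel UMIs. The fibrous share was 0% at Leiden 0.3, 9.19% at Leiden 1, 4.98% with k-means and 7.47% at 10 panel UMIs. Muscle was 0.977% at 50 and 2.88% at 10 panel UMIs, epithelium 0.849% with k-means and 1.37% at 50 panel UMIs, and blood 0% at Leiden 0.3 and at 50 and 10 panel UMIs.

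Among named genes and alternatives other than leaving out a frame, 878 of 907 values kept direction and call in the inner retina, 905 of 981 in the coat, 652 of 779 in the ganglion comparison and 603 of 651 in the myelin comparison. With each frame left out these were 275 of 287, 257 of 287, 221 of 263 and 96 of 154. In total 188 values of named genes could not be given under an alternative. Of the lists that passed by camera at the preset correlation, 76 of 94 values still passed for the inner retina, 164 of 185 for the coat, 48 of 48 for the ganglion and 94 of 95 for the myelin comparison, but 0 lists passed with an estimated correlation. The myelin comparison was not run at 50 panel UMIs, where too few frames were left. In the myelin comparison the median log2 fold of all genes was -0.63, and -0.45 with plain library sizes, so its folds are relative to TMM.

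Calls of single genes were ended, or turned in sign, in at least 2 settings or left-out frames as follows. In the inner retina these were Tcf4 (8), Foxc1 (7), Gadd45a (6), Ctnnb1 (4), mt-Co2 (4), Apoe (3), Lamb2 (3), C3 (2) and Hspa5 (2). In the coat they were Rbp3 (13), Aipl1 (13), mt-Nd4l (12), mt-Nd1 (10), Atp5j2 (10), Lgr4 (8), Atp5e (8), Jchain (6), Hspa5 (5), Gfap (3), Foxc1 (3), Igkc (3) and Rdh10 (2). In the ganglion comparison they were Hspa5 (13), mt-Nd4 (13), mt-Nd6 (13), Tyrobp (12), Atp5e (11), Ryk (9), Vwf (9), Ctss (8), Rgs5 (8), Ptprc (7), B2m (6), Igkc (6), Ndufa4 (6), Myh11 (5), mt-Cytb (4), Btg2 (4), Nmnat2 (4), Dkk3 (3), Gfap (3), Ighg2c (2), Trf (2) and Lamb2 (2). In the myelin comparison they were mt-Nd1 (9), mt-Co2 (8), Timp3 (8), Tyrobp (7), Atp5j (6), Ptprc (6), mt-Co1 (5), Scd2 (5), Serping1 (4), Gnb1 (3), Sncb (3), Vamp2 (3), Celf4 (2), Atp2b2 (2), Trarg1 (2), Stmn4 (2), Kif5a (2), Bsg (2), Gapdh (2), Tpi1 (2), Scd1 (2) and Gria1 (2). For lists by camera they were microglia (10), interneuron (7), visual cycle (3) and immunoglobulin genes (2) in the inner retina, interneuron (10), oxidative phosphorylation (9), endothelium (4) and Wnt target genes (2) in the coat and mitochondrially encoded genes (2) in the myelin comparison.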

Other observations

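The comparison of myelin and ganglion regions, with all its tests, was chosen only after the result was seen. The tests of Rpl4 and Rpl23 were set after the high levels of these genes were seen, but before the outcomes of the tests. In the myelin region, led by Mobp and Mbp, 8 of 10 gliosis genes were higher than in the ganglion region (frames 2, 3 and 4, n = 3). Their list passed camera at the preset correlation but not with an estimated correlation (camera adjusted p = 0.209). The myelin panel genes drew the region and were not tested. Gfap reached 7278 ± 2660 against 297 ± 32.4 CPM, a log2 fold of 4.59 ± 0.536 (higher in 3 of 3 frames, edgeR quasi-likelihood test with Benjamini-Hochberg adjusted p = 6.97e-31). Snap25 fell to 433 ± 213 from 7753 ± 408 CPM (-4.26 ± 0.297, lower in 3 of 3 frames). In total 345 of 1645 genes passed, 145 higher and 200 lower (42.0% higher, and 14.2% without the filter on low counts). The region holds 78 spots and 39753 UMIs, and 46 genes passed without frame 3 and 110 without frame 4.

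Among the largest folds toward the myelin region, Bcas1, a gene of myelinating glia, had 28 UMIs against 0, at least 149-fold higher against a floor of 3 UMIs over the ganglion region. That number leaves out counting error of the 28 UMIs. The myelin membrane gene Mal had 30 UMIs against 3 (ratio 160.0, interval 49.7 to 819) and the growth factor receptor gene Fgfr2 13 against 2 (ratio 104, interval 23.5 to 949). Tmem88b (6.65 ± 1.05), the complement gene C4b (6.08 ± 0.632), Cd109 (5.99 ± 0.641), S1pr3 (5.96 ± 0.32), the creatine gene Gatm (5.87 ± 1.47), Ndrg1 (5.74 ± 1.25) and the tetraspanin gene Tspan2 (5.67 ± 1.16) were also higher in 3 of 3 frames. Several genes were at 0 UMIs in the myelin region: Calb2 was at least 9.65-fold lower, Gpr153 at least 9.42, Napb at least 9.11, Pcp4 at least 8.46, Zwint at least 7.32, Celf4 at least 7.04, Bnip3 at least 7.002, Atp2b2 at least 6.90 and Trarg1 at least 6.25, against a floor of 3 UMIs over the region. Each of these 9 calls ended in 1 or 2 of the 3 fits with a frame left out.

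Of 10 gliosis genes 8 rose in the myelin region, including Vim (4.43 ± 0.878), Mt2 (3.26 ± 0.57) and Apoe (3.10 ± 0.454), with camera adjusted p = 4.62e-14 (adjusted p = 0.209 with an estimated correlation). Visual cycle and pigment epithelium genes rose in 6 of 7, such as Ptgds (3.51 ± 1.42), Trf (4.29 ± 1.31) and Enpp2 (3.76 ± 1.53), which glia of the optic nerve are known to share (camera adjusted p = 3.18e-08, and adjusted p = 0.335 with an estimated correlation). Microglia and complement genes rose in 3 of 7 (Serping1 2.67 ± 0.64, Tyrobp 1.82 ± 0.236, camera adjusted p = 0.00108, and adjusted p = 0.394 with an estimated correlation) and mitochondrially encoded genes in 6 of 11 (mt-Co1 1.30 ± 0.48, camera adjusted p = 0.00159, and adjusted p = 0.573 with an estimated correlation). Tyrobp did not pass in 4 of 11 other settings or with any 1 of the 3 frames left out, and Serping1 did not pass under DESeq2 (2.29), without the filter (1.39) or without frame 3 (2.36) or 4 (2.06). Without the filter mt-Co1 was 0.026, and it did not pass under DESeq2 (0.92), with panel genes in the library sizes (1.11) or without frame 3 (1.16) or 4 (0.90). Synaptic genes fell in 9 of 15, with Vamp2 at 1 UMI against 265 (ratio 16.6, interval 2.95 to 656.8) and Sncb at 0 (at least 3.38-fold lower), and glycolysis genes in 7 of 17, with Gapdh at -1.83 ± 0.98 and Bsg at -1.30 ± 0.406. Both lists had camera adjusted p = 0.00277 (adjusted p = 0.573 and 0.394 with an estimated correlation). Vamp2 and Sncb did not pass with any 1 of the 3 frames left out.

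Axon genes divided in the myelin region, 5 of 22 higher and 7 lower. Stmn4 (2.48 ± 0.63) and Kif5a (2.86 ± 0.525) rose, while Crmp1 had 2 UMIs against 705 (ratio 22.0, interval 6.08 to 182.3). The 2 tested Wnt target genes, the transcription factor gene Sp5 (4.74 ± 0.589, 13 UMIs against 7) and the cell cycle gene Ccnd1 (4.09 ± 0.405, 9 against 12), both rose. In addition, Tgfb2, a glaucoma-associated growth factor gene, rose by 3.93 ± 0.602. Tcf4 did not pass (1.27 ± 0.696, edgeR quasi-likelihood adjusted p = 0.321). Matrix genes rose in 2 of 5, Col6a2 (3.60 ± 1.43) and Timp3 (2.40 ± 0.618), with camera adjusted p = 0.00562 (adjusted p = 0.394 with an estimated correlation). Timp3 did not pass in 5 of 10 other settings or with any 1 of the 3 frames left out. Sterol and fatty acid genes rose in 2 of 9, Scd1 (3.41 ± 0.809) and Scd2 (2.04 ± 0.602), but Scd2 did not pass with any 1 of the 3 frames left out. Oxidative phosphorylation genes fell in 2 of 22, among them Ndufa4 (-1.32 ± 0.417), and Gnb1 was the 1 of 6 phototransduction genes that fell (-1.44 ± 0.271). Of 4 interneuron genes 1 rose and 1 fell, and the one that rose, Gria1 (3.18 ± 1.32), did not pass without the filter (1.98) or without frame 3 (1.97). Igkc (2 UMIs against 831, ratio 25.98, interval 7.17 to 214.9) and Ptprc (1 against 250, ratio 15.6, interval 2.78 to 619.8) fell. Ptprc did not pass in 3 of 12 other settings or with any 1 of the 3 frames left out. Adjusted over the list alone, the counts became 4 higher for matrix, 8 higher and 2 lower for gliosis, 8 lower for glycolysis, 6 higher for microglia, 7 higher for mitochondrially encoded genes, 5 higher and 8 lower for axon genes, 11 lower for synaptic genes, 1 higher and 2 lower for interneuron genes, 1 lower for oxidative phosphorylation and 7 higher for visual cycle genes.

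Rpl4 and Rpl23, genes chosen after their values were seen, stood far above other ribosomal protein genes. Rpl4 had 80413 UMIs (2.28% of all) and Rpl23 57728, against a median of 990 over 77 ribosomal protein genes and 14705 for Rpl8. A fault of a single frame is argued against by the lowest ratio of either gene to the median over the 4 frames, 51.15, and RNA from 1 region or a few spots by a highest over lowest of the 5 largest regions of 1.44. What stays open is a technical source common to all frames, such as capture at particular sequences or counting of related sequences, and no biological explanation was tested. Gm42418, a transcript that overlaps ribosomal RNA and was chosen after its value was seen, had 72846 UMIs (2.07%), and the 10 highest genes took 11.6% of all UMIs.

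The layout of tissue on the frames was alike in frames 2, 3 and 4. They shared 761 (frames 2 and 3), 746 (2 and 4) and 824 (3 and 4) positions over tissue, or 49.5%, 46.6% and 61.7% of the positions covered by either, against 13.5%, 10.8% and 14.9% for frame 1 with frames 2, 3 and 4. At shared clustered positions of frames 2, 3 and 4 the region was the same in 28.3%, 28.4% and 37.9%, against 18.6%, 20.3% and 19.6% by permutation (adjusted permutation p = 0.0003, 0.0006 and 0.0003, where 0.0001 is the smallest unadjusted value that 10000 permutations can give). For frame 1 the values were 19.4%, 17.3% and 27.3% against 18.7%, 16.3% and 19.4% (adjusted permutation p = 0.5, 0.48 and 0.03). Neighbouring spots often hold the same region. The permutation treated spots as independent, so these p-values may be too small. Whether frames 2, 3 and 4 hold sections of different animals or of neighbouring tissue was not tested here, and the labels call each a separate replicate. The labels name nuclear RNA as the molecule, while mitochondrially encoded genes took 2.44 to 2.82% of UMIs per frame.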
